A study of Zea mays with 6 samples.

How the data were processed

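Leaf RNA of maize seedlings 2 weeks old was measured by poly(A)-selected RNA sequencing in 6 libraries, 3 of the inbred line KN5585 and 3 of a line in that background with ZmPP2C45 edited to a knockout, called WT and PP2CKO in the labels. The labels number the libraries of each line from 1 to 3 and do not say whether the numbers mark separate plants or pools, so p-values measure only the spread between these libraries, which may be technical.

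The authors deposited a table of raw counts per gene, 1 column per library, that was not normalized. Per the labels' protocols, adaptor and low-quality reads were removed and the rest were aligned to the B73 v4 genome with STAR 2.4.0j. The counting tool, the annotation release and the strand setting are not given in the sources used here, so reads of a gene and of an overlapping or antisense partner, or of near-identical copies, may have been assigned together. Both lines were aligned to the genome of another inbred line, so genes that diverge from B73 may be undercounted in both lines alike. The table held 45953 features, of which 43789 were nuclear gene models and 1645 were other noncoding RNA identifiers. A further 154 were microRNA precursors and 365 were organelle genes. Of all features, 16874 had a count of 0 in every library. Rows naming no gene were not present. Library totals ran from 15923668 to 20502449 counts.

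The gene table used here for names follows assembly Zm-B73-REFERENCE-NAM 5.0. It matched 365 of 365 organelle identifiers and 153 of 154 microRNA identifiers, but 0 of 43789 nuclear gene models, and the count table does not pair its identifiers with names. Nuclear genes are therefore given by identifier, without names or coordinates, and checks of GC content or gene length were not made. ZmPP2C45 itself and ZmBELL4 were not analysed here under their own names, so the label of the knockout was not checked at the level of its transcript.

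Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with genotype as the only term. Features were kept by filterByExpr with its default minimum count of 10 and minimum total of 15, which left 21206. Scaling was by trimmed mean of M values (TMM), and CPM values are counts divided by the library totals after that scaling. A feature was called at a Benjamini-Hochberg adjusted p below 0.05, with no minimum fold. Principal components and sample correlations used log2 CPM with a prior count of 2. Library measures such as total counts were compared by exact permutation of the 6 labels, two-sided, for which the smallest possible p is 0.1. On simulated counts for the tested features of this comparison, with 20835 features passing the filter, the procedure called 47% of 100 features seeded at 2-fold and 85% of 100 seeded at 4-fold. It called 0.0238% of the 21006 features simulated without a change.

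Choices made before the data were examined were the test, the alternatives named in the closing section unless stated otherwise, 37 gene lists and the rule for naming genes. The rule named the targeted gene where a name identified it, the members of the benzoxazinoid list, and the genes of largest change among those called. For the largest changes it asked for a mean of at least 1 CPM in the higher group and no overlap between the groups. Where the reference gave no names, it allowed 2 identifiers that were higher and 2 that were lower. Of the 37 lists, which covered benzoxazinoid, jasmonate, terpene, hormone, photosynthesis, clock and other groups, 35 had no member that could be matched. The other 2, chloroplast-encoded and mitochondrion-encoded genes, had 1 tested member each. None reached the 5 tested members set for a list test, so the list tests by camera and fry, and the test of calls by chromosome, were not run.

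A fold against a group with no counts was computed against a floor of 3 counts over the group's 3 libraries and is a lower bound. Ratios with 1 count in a group carry the exact (Clopper-Pearson) 95% interval of the counts. Such intervals and floors cover counting error only, since the reads carry no molecular identifiers. DESeq2 1.42.0 and limma 3.58.1 (voom) served as alternative tests, and each library was left out in turn.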

Results

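Transcript abundance was compared in leaves of 2-week-old maize seedlings between the inbred line KN5585 (WT, n = 3) and a genome-edited line in the same background in which ZmPP2C45 was knocked out (PP2CKO, n = 3). Protein phosphatases 2C are serine/threonine phosphatases, and members of this family act in plant hormone and stress signalling. The title of the series places ZmPP2C45 and the homeodomain protein ZmBELL4 in the control of chemical defence against insect herbivores. The comparison asks which leaf transcripts differ when ZmPP2C45 is lost.

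The WT libraries held 16368195, 15928973 and 15923668 counts, and the PP2CKO libraries held 17971317, 16314657 and 20502449. The mean totals of 16074000 ± 255100 and 18263000 ± 2109000 (SD, n = 3 each) gave p = 0.2 in an exact two-sided permutation test, for which the smallest possible p is 0.1. Between 24966 and 25439 features had at least 1 count in a library. Nuclear gene models took 99.97% of all counts. Replicates of one line differed by more than sampling noise, with a chi-square per degree of freedom of 19.23 to 26.28 between libraries of the same line and 45.64 to 82.32 between lines. No library was therefore counted as a second copy of another. Pearson correlations of log2 CPM across genes were 0.951 to 0.968 within a line and 0.923 to 0.951 between lines. The first principal component carried 44.0% of the variance and placed the 3 WT libraries between -50.1 and -34.6 and the 3 PP2CKO libraries between 22.6 and 59.98.

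**Figure D1:**
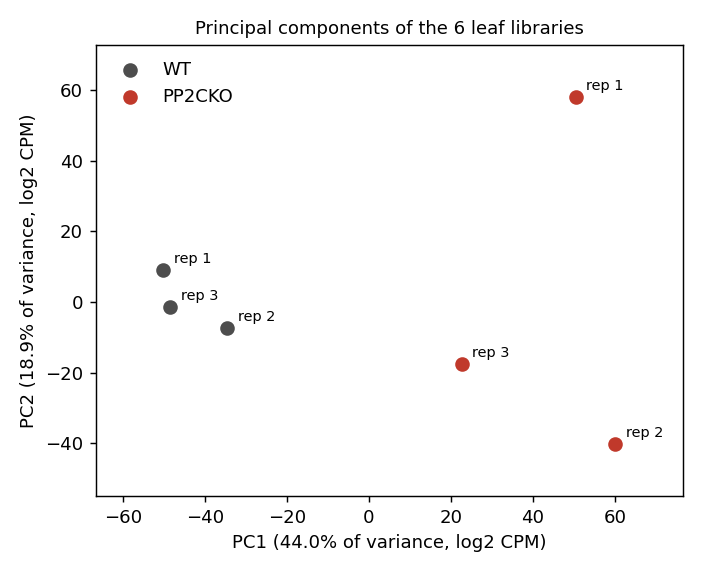
Each point is 1 library, placed by its first and second principal component of log2 CPM (axes give the percent of variance); grey is WT and red is PP2CKO. The lines separate along the first component, where PP2CKO replicate 3 at 22.6 lies nearest to WT, and PP2CKO replicates 1 and 2 part along the second at 58.1 and -40.3.

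Leaves of the knockout differed from WT in 1534 of 21206 tested genes, or 7.23%. Of these, 1092 genes were higher in PP2CKO and 442 were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Genes that were higher had a median rise of 2.16-fold, with an interquartile range of 1.76 to 3.42. Genes that were lower had a median decrease of 1.79-fold, with an interquartile range of 1.61 to 2.20. In 1516 of the 1534 called genes, or 98.8%, the 3 libraries of one line did not overlap those of the other. Among all tested genes that share was 28.2%, and chance alone would give 10%. The genes were called on these same libraries, so the 98.8% follows largely from the test and is no separate support for the calls.

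Increases outnumbered decreases at each fold bound, but their share did not keep rising among the largest changes. Among genes that changed by over 2-fold, 628 were higher and 142 were lower in PP2CKO. Over 4-fold, 225 were higher and 35 lower, and over 8-fold, 72 were higher and 18 lower. The share of calls that were increases was 71.2% at any fold and 81.6% over 2-fold. The split over all calls depended on the scaling: with library size alone, 680 genes were higher and 1604 lower, or 29.8% higher. That scaling moved the median log2 fold change of all tested genes by -0.22. Over 2-fold, library size alone gave 426 higher and 391 lower genes. The directions are thus stated relative to the bulk of tested genes, as TMM scaling sets it.

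**Figure D2:**
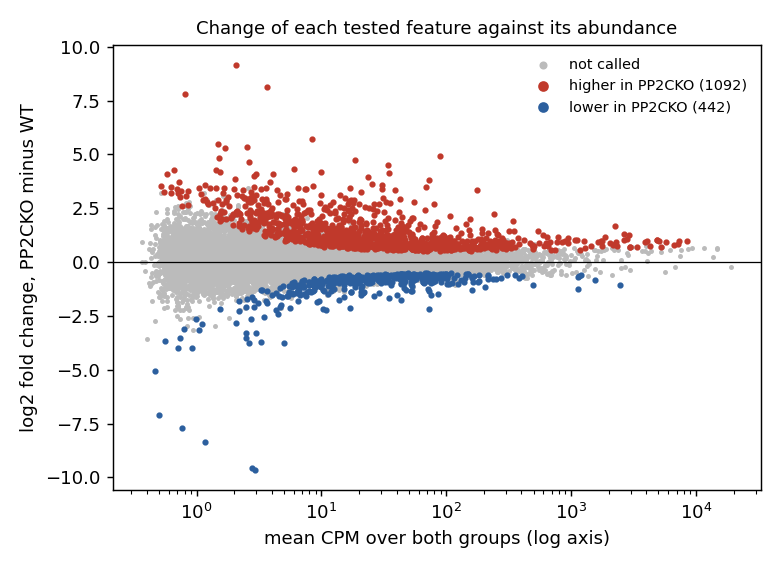
Each point is 1 of 21206 tested features, with its mean CPM over both lines on a log axis and its log2 fold change (PP2CKO minus WT) on the other axis; red marks the 1092 called higher, blue the 442 called lower and grey the rest. Called increases extend over the whole range of abundance, and the lowest points, below -7, are genes with no counts in PP2CKO.

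Calls were more frequent among abundant transcripts, for which higher counts also make a change easier to call. Whether abundant transcripts were changed more often was not tested. Tested genes were ranked by abundance and parted into 4 bins of equal size. In the bin of lowest abundance, with a median of 1.70 CPM, 3.45% of genes were called, and in the bin of highest abundance, with a median of 57.2 CPM, 11.8% were called. Of called genes in these 2 bins, 80.3% and 69.7% were increases. The 20 most abundant transcripts took 18.9% ± 0.314 of the counts in PP2CKO and 15.8% ± 2.13 in WT (SD, n = 3 each). This difference reached p = 0.1 in the exact permutation test, the smallest that 3 against 3 libraries allow. Of these 20 transcripts, edgeR called 6 higher and 0 lower, and at an unadjusted p below 0.05 it put 15 higher and 0 lower. DESeq2 called 14 higher and 0 lower, and limma voom 7 and 0. Their median log2 fold change was 0.63 (range -0.48 to 0.99), and with library size alone it was 0.41, with 10 called higher and 1 lower.

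The count of calls was lower without any 1 of the libraries except PP2CKO replicate 3. Without WT replicate 1, 475 genes were higher and 116 lower. Without WT replicate 2 the counts were 570 and 286, and without WT replicate 3 they were 339 and 123. Without PP2CKO replicate 1 they were 878 and 257, without PP2CKO replicate 2 they were 662 and 223, and without PP2CKO replicate 3 they were 1141 and 409. PP2CKO replicate 3 had the highest value of its line in 10.1% of the genes called higher, against 45.6% for replicate 1 and 44.3% for replicate 2. The median log2 difference of these genes from the WT mean was 0.89 in PP2CKO replicate 3, 1.12 in replicate 1 and 1.21 in replicate 2.

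A few transcripts were present in one line and had no counts in the other. With a minimum of 1 CPM in each of 3 libraries, 4 genes were expressed in WT and had 0 counts in every PP2CKO library. In the reverse direction, 2 genes were expressed in PP2CKO and had 0 counts in every WT library. None of the 9 other ways to part the 6 libraries into 3 and 3 gave such a gene (highest 0), but each of them mixes the lines, so a gene present in 1 line alone cannot appear there.

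The genes of largest change are given by identifier. Zm00001d029481 averaged 5.87 ± 0.848 CPM in WT and had 0 of its 305 counts in PP2CKO, at least 99.6-fold lower (edgeR adjusted p = 0.000258). Zm00001d030099 averaged 5.54 ± 0.672 CPM in WT, with 288 counts there and 0 in PP2CKO, at least 94.0-fold lower (edgeR adjusted p = 0.000266). Zm00001d030914 averaged 7.33 ± 0.665 CPM in PP2CKO, with 374 counts there and 1 in WT, in replicate 3. Its ratio of 382 rests on that 1 count, with a 95% counting interval of 68.1 to 15100 (edgeR adjusted p = 9.54e-05). Without WT replicate 3 no WT count is left, and the fitted log2 fold change moved from 8.12 to 9.95 (edgeR adjusted p = 0.00137). Zm00001d002618 had 202 counts in PP2CKO and 0 in WT, at least 68.7-fold higher (edgeR adjusted p = 0.00499). Its level was uneven among the PP2CKO libraries, at 1.15, 9.06 and 2.29 CPM, which gave a mean of 4.17 ± 4.27 (SD; n = 3 per line for all 4 genes). PP2CKO replicate 2 held 68.3% of these counts, and without it the bound was 31.1-fold. The floor of 3 counts corresponded to 0.0577 CPM in WT and 0.0589 CPM in PP2CKO.

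**Figure D3:**
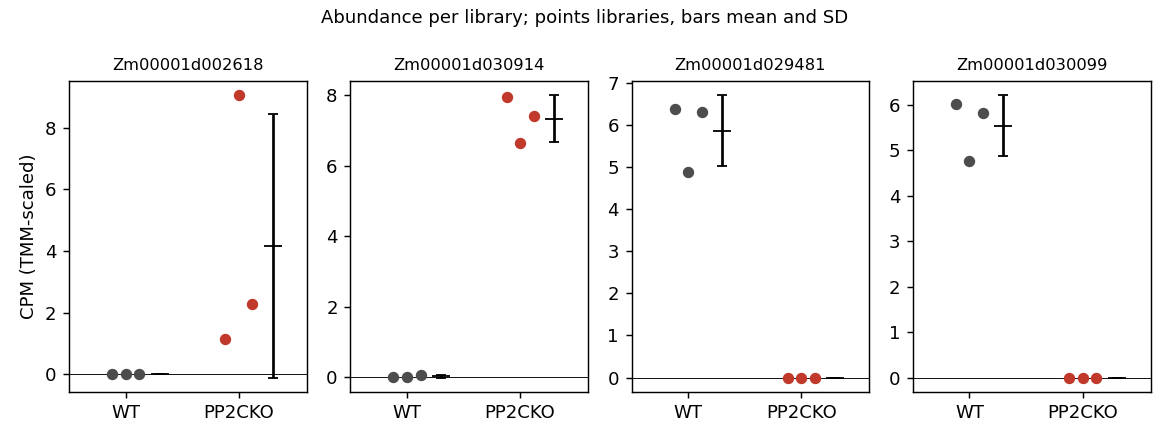
Each panel is 1 gene, with TMM-scaled CPM on the vertical axis from 0; points are single libraries (grey WT, red PP2CKO) and the black bars give the mean and SD of 3. Zm00001d029481 and Zm00001d030099 lie at 0 in every PP2CKO library, and Zm00001d002618 lies at 0 in every WT library with values from 1.15 to 9.06 in PP2CKO.

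Organelle transcripts, which poly(A) selection largely removes, did not pass the test in either direction (edgeR, 0 of 6 tested genes over all genes tested, 2 at an unadjusted p below 0.05). limma voom also called 0, and DESeq2 called 2, rrn26 and matK, both higher in PP2CKO. The mitochondrial 26S ribosomal RNA gene rrn26 was at 142 ± 27.3 CPM in WT and 234 ± 71.2 CPM in PP2CKO (log2 fold change 0.72 ± 0.23 SE, edgeR adjusted p = 0.0754). matK, a plastid gene for an intron maturase, was at 0.794 ± 0.358 and 2.61 ± 1.06 CPM from 169 counts in all (log2 fold change 1.70 ± 0.55 SE, edgeR adjusted p = 0.0828). It was the 1 tested member of the fixed list of chloroplast-encoded genes, so its value adjusted over the list alone is the unadjusted edgeR value (adjusted p = 0.00885) and is no test of the list. cox1, which encodes a subunit of cytochrome c oxidase, was the 1 tested member of the mitochondrial list. It had a log2 fold change of 0.61 ± 0.80 SE, and its value adjusted over the list alone is likewise the unadjusted one (edgeR adjusted p = 0.461). The mitochondrial 18S ribosomal RNA gene rrn18 had 10.8 ± 2.77 CPM in WT and 11.9 ± 6.29 CPM in PP2CKO. The plastid gene ycf3, whose product acts in photosystem I assembly, had 6.25 ± 3.09 CPM in WT and 4.41 ± 0.563 CPM in PP2CKO (SD, n = 3 each).

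All plastid features together took 9.92 ± 4.58 CPM of the unscaled totals in WT and 9.47 ± 0.913 in PP2CKO (exact permutation p = 1, two-sided). All mitochondrial ribosomal RNA took 166 ± 38.4 and 226 ± 62.6 CPM of the unscaled totals (exact permutation p = 0.3, two-sided). MIR482 was the 1 microRNA precursor deep enough to test, at 1.97 ± 0.749 CPM in WT and 1.84 ± 1.56 CPM in PP2CKO (edgeR adjusted p = 0.952). Mature microRNAs were not measured by these libraries.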

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

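The 4 named genes kept their direction and stayed past the threshold in all 80 combinations of gene and alternative, with a highest adjusted p of 0.031. They were chosen as the largest called changes in these same data, so their stability says nothing about other calls. The alternatives of a fold above 2 and an adjusted p below 0.01 reused the main fit with stricter thresholds. No gene called in an alternative had been called in the opposite direction. RLE size factors, upper-quartile scaling, a minimum of 1 CPM, limma voom and robust edgeR left both counts within 1.5 times of 1092 higher and 442 lower. Library size alone gave 680 and 1604, and of these 671 and 442 were among the original calls. No low-count filter gave 1672 and 781, a fold above 2 gave 628 and 142, and an adjusted p below 0.01 gave 326 and 68. DESeq2 called 1527 higher and 705 lower, with 412 adjusted p-values not given. Leaving out 1 library gave 339 to 1141 higher and 116 to 409 lower genes; these fits have fewer libraries by construction, and no other cause was tested. For the other settings the cause was not tested, except that the stricter thresholds remove calls by construction. A replicate block, which takes the shared replicate numbers as pairs, gave 1323 and 537. Deviations of same-numbered libraries correlated at 0.0525, 0.0888 and 0.0847, each below the 0.1 set for pairing, so the numbers were not taken to pair the libraries. Every library nevertheless correlated best with its own number, and all pairs with different numbers correlated negatively, at -0.0705 to -0.00985. Deviations were taken from the mean of each line, so positive values for equal numbers force negative ones elsewhere on balance. The negative values are thus no separate evidence. Whether the numbers mark a shared batch therefore stays open. Another 3 settings were chosen after seeing the data: thinning to 15923668 counts per library gave 1089 and 451, leaving out the 100 most abundant features gave 1051 and 427, and doing so with library size alone gave 874 and 656. At the depth, spread and number of libraries at hand, simulated 2-fold changes were called in 47% of cases, so a gene that was not called is not shown to be unchanged. The simulation changed far fewer features, 100 at each fold, than the 1534 called here. That makes its adjusted threshold stricter, so the share called in the data may differ from 47%.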

Other observations

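The tests of consecutive identifiers by shuffling and by windows, and both tests of where the largest changes lie by placement and by the calls around them, as well as the intervals and the correction for counting noise of the neighbour correlations, were chosen after the result was seen. The 10 ways to part the 6 libraries into 3 and 3 are too few for a share under 0.05. The real grouping, 1 of the 10, called 1534 genes, and the highest of the other 9 called 0 (edgeR, with 362 to 1387 genes at an unadjusted p below 0.05, against 4927). Each of the other 9 mixes the lines, so the difference between lines adds to the spread within its groups. Few calls are expected there by construction, and the 0 gives no support to the real grouping.

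The excess of increases in PP2CKO was weighed against technical explanations. Greater depth of the PP2CKO libraries is argued against, since 70.7% of calls were increases after thinning all libraries to the same total. A single deviant library is argued against by the share of 66.6% or more whichever library was left out. The scaling met the condition set for it before the test over all calls, since library size alone gave 29.8% increases. Upper-quartile and RLE scaling gave 73% and 71.6%. Over 2-fold, library size alone gave 52.1%, between the bounds set. Scaling may therefore account for the excess over all calls, and it stays open over 2-fold. Without the 100 most abundant features, which took 35.2% of all counts, library-size scaling gave 57.1% increases, between the bounds set for a part played by these features, so whether they may account for the difference cannot be told apart from a broader shift. A real excess of increases in the knockout remains an untested biological explanation.

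Called genes with consecutive identifier numbers tended to change in the same direction. Of 10179 such pairs of tested genes, 71 were called in the same direction, 2.26 times the mean of 31.5 from shuffled calls (p = 1e-04, the smallest 10000 shuffles can give, permutation test), and 16 in opposite directions against 21.9. The excess was 1.36 times for numbers 2 to 5 apart and was not seen at 6 to 20 (0.987 times) or 21 to 50 (1.04 times, permutation p = 0.155). Tested genes in order of identifier were cut into 422 windows of 50 without overlap, so a cluster across an edge would be split. The fullest of these windows held 10 calls against a shuffled mean of 10 (95% point 12, permutation p = 0.696), so no crowding of calls was seen in them. This does not decide on a long segment that differs between the lines, since the share of calls it would give is not known. General co-variation of neighbours stays open. The Spearman correlation across genes between consecutive identifiers was 0.0918 between lines and 0.042 to 0.0663 in the 6 contrasts of 1 library with the others of its line, so the bound set before the test, that every contrast within a line lies below, was met, but not by more than its spread. The difference from the highest, PP2CKO replicate 1, had a 95% interval of -0.000786 to 0.055 (1000 resamples of blocks of 50 pairs). With counting noise removed by halving the counts, the values were 0.101 and 0.0843 (interval of the difference -0.0125 to 0.0501). Reads shared between tandem copies, or joint regulation of neighbours in the knockout, may underlie the pairs; neither was tested, and the positions behind the identifiers were not used here.

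The largest changes were unevenly placed among the identifiers. Of 13 nuclear genes with a fitted log2 change beyond 5, 7 were higher and 6 lower in PP2CKO. Among the 13, 6 lay between the numbers 29480 and 31032, which hold 2.39% of tested genes. Of these 6, 5 were lower in PP2CKO and 1 was higher, and they include Zm00001d029481, Zm00001d030099 and Zm00001d030914. Random placement gave a mean of 2.71 in the fullest stretch of 2000 numbers (permutation p = 7e-04); with bounds of 3, 4 and 6 on the log2 change the permutation p was 0.298, 0.0159 and 0.001. At the other line's level 46 to 856 counts were expected in the lower line, where at most 16 were seen and 7 of the 13 genes had 0. These 13 genes were picked for a large change in the same counts, so low counts against the expected ones were fixed by the choice. The bound of 10 set before the test was met, but a fitted change beyond 5 with no counts in the lower line already needs 12.3. Too few reads therefore cannot be judged from these genes. Of the other genes in the stretch, 7.20% were called (95% exact interval 5.09 to 9.83) against 7.19% elsewhere, below the bound of double that share, 14.4%. The bound was chosen after seeing the data and the share a different haplotype would give is not known, so it stays open. Another candidate explanation that stays open is that a few genes in this stretch are deleted, inserted or silenced in one of the lines, which genome sequence of both would test.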
